A study of Azoarcus olearius with 5 samples.

How the data were processed

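The data are RNA-seq counts of 5 libraries of Azoarcus olearius BHΔrnc, 3 from growth with ammonium and 2 from N2-fixing growth. Per the labels, RNA was extracted with hot phenol, depleted of rRNA and fragmented, and an adapter ligated to the 3' end of the RNA kept the strand. The cDNA was amplified in 13 PCR cycles and read at 75 bp. No molecular identifiers are mentioned, and PCR reads without them are not independent molecules, so counting error alone understates the uncertainty of small counts.

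The deposited table holds estimated counts per annotated feature, not normalized, in steps of 0.5. It gives each feature's type, strand, start and end on 1 chromosome sequence, AM406670.1, and all positions in the report are those, counted from 1. Per the submitters' processing notes, fastp and DESeq2 were used, with no version or role. The aligner, the counting tool and the source of the ncRNA annotation are not given in the sources used here. Fractional counts occurred in 2858 features, each with a neighbour on its own strand closer than 1 read length, and in 0 features without one. The 739 antisense ncRNAs without such a neighbour held 0 fractional counts although each overlaps a CDS, so the counting used the strand. A read that touches a pair of close features on the same strand was thus shared between them, and values of adjacent features in an operon are not fully independent. Counts were rounded to whole numbers for the tests, fractions upward.

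Features were sorted into 3989 CDS, 56 tRNA and 927 ncRNA features by the table's own types. An ncRNA was called antisense when it overlaps a CDS on the opposite strand by 1 nt or more (798 features, 593 of them fully opposite the CDS) and was paired with the CDS of largest overlap. It was called intergenic when it overlaps no CDS (128 features); the remaining 1 overlaps only a CDS of its own strand. Annotated ncRNA lengths run from 31 to 1905 nt, with a median of 82 nt for antisense features.

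The main test was edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr, a robust quasi-likelihood fit on the growth condition and Benjamini-Hochberg adjustment, with tRNA rows left out of library sizes and the test. Features were called at an adjusted p under 0.05, and log2 fold changes are N2-fixing over ammonium. CPM values use the TMM-scaled library sizes. Standard errors are the log2 fold change divided by the square root of the F statistic. For the antisense test the antisense rows were fitted with the library sizes and TMM factors of the CDS rows. The change of an antisense ncRNA relative to its CDS was the interaction of strand and condition in 1 edgeR fit with libraries as blocks. tRNA rows were tested in a fit with all rows. Classes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset correlation of 0.01 and again with an estimated one. Shares of counts were compared by exact permutation tests, directions of pairs by Fisher's exact test, and relations across features by Spearman's rho with 10000 permutations and 2000 bootstrap draws for 95% intervals (scipy 1.17.1, pandas 2.3.3, Python 3.11.15). Features are not independent replicates, so p-values across features describe these libraries. Figures were drawn with matplotlib 3.10.9.

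The design, the main test and most alternatives were set before the data were examined. The rule for named genes took the 10 largest rises and the 10 largest falls among called features whose groups do not overlap and whose mean is 50 CPM or more in a group, plus rnc, the nif genes and members of fixed gene lists. The table pairs CDS identifiers with no names or products, and no annotation was used here, so the gene lists, rnc and the nif genes are not reported, and only the first 2 CDS of each direction are named. Antisense and intergenic features were picked by the size of their change or their abundance after seeing the data, as were tRNA genes, runs of at least 7 CDS and the pairing of directions. The main stretch joins the longest run of higher CDS with the other higher runs less than 10 kb away. Runs were compared with 10000 shuffles of the calls along the genome.

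The fits were tested on simulated counts drawn from the means and library sizes of these libraries. Among 4833 simulated CDS and ncRNA rows, 34% of the changes of 1.5-fold, 63% of those of 2-fold, 99% of those of 4-fold and 100% of those of 8-fold were recovered, and 4.98% of the calls were unchanged rows. Of these rows 4533 were simulated without a change. Changes were thus rarer than the calls in the real libraries, where recovery may differ. The changed CDS, ncRNA and antisense rows were drawn only from rows above a minimum mean count. Recovery among sparser rows may be lower. Among 798 antisense rows, 9.09% of the 11 changes of 1.5-fold, 63.5% of the 2-fold and 98.3% of the 4-fold changes were recovered, with 6.96% of the calls on unchanged rows. For antisense relative to CDS the shares were 54.0% and 97.2%, and for tRNA rows 95% at 2-fold. With no change simulated, 0 rows were called in each of the 4 settings. The alternatives were DESeq2 (1.42.0), limma-voom, median-ratio size factors, total counts without TMM, no filter, a filter of 10 CPM in 2 libraries, the 10 most abundant features left out, tRNA rows kept, a replicate block, and each library left out in turn. Alternatives added after seeing the data were a stricter definition of antisense (at least 0.5 of its length opposite a CDS), features with a close neighbour left out, and fractions rounded down.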

Results

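Transcript levels were measured by directional RNA sequencing in Azoarcus olearius BHΔrnc, a mutant of the nitrogen-fixing betaproteobacterium BH72 that lacks RNase III, the endonuclease that cuts double-stranded RNA. Cells grew in a stirred bioreactor at 37 °C under 0.3% oxygen, either with 10 mM ammonium chloride (3 libraries) or without it, so that N2 was the nitrogen source (2 libraries). All 5 libraries came from the mutant. The deposited counts summed to 7566502, 7078544 and 7678049 in ammonium replicates 1, 2 and 3, and to 6862752 and 6904094 in N2-fixing replicates 1 and 2. They covered 3989 coding sequences (CDS), 927 noncoding RNA (ncRNA) features and 56 tRNA genes. CDS took 93.8% ± 0.791 of the counts in ammonium libraries (SD, n = 3) and 95.5% ± 0.0642 in N2-fixing libraries (SD, n = 2). The first principal component of the log2 CPM (counts scaled to library size) held 87.8% of the variance and parted the growth conditions. The second held 6.24% and mainly parted the 2 N2-fixing libraries from each other. Spearman correlations were 0.992 to 0.994 among the ammonium libraries, 0.983 between the N2-fixing libraries and 0.890 to 0.914 across conditions. Replicates differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 23.2 or more, so no library was counted double.

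The main comparison asked which RNAs differ when the mutant grows on N2 in place of ammonium. The largest change lay in 1 stretch of the chromosome, at 546104 to 599704, where 53 of 59 CDS rose under N2 fixation, 0 fell and 6 were not called. The median log2 fold change over these 59 CDS was 6.15, and 45 of them had a value of 4 or more. Of the 47 CDS in the genome with a log2 fold change of 6 or more, 32 lay here. The stretch took 0.0855% ± 0.00317 of all counts with ammonium (SD, n = 3) and 4.23% ± 0.396 under N2 fixation (SD, n = 2). Both strands took part: the 31 adjacent CDS at 571215 to 599704, 11 on the plus and 20 on the minus strand, all rose, with a median of 6.88.

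**Figure D1:**
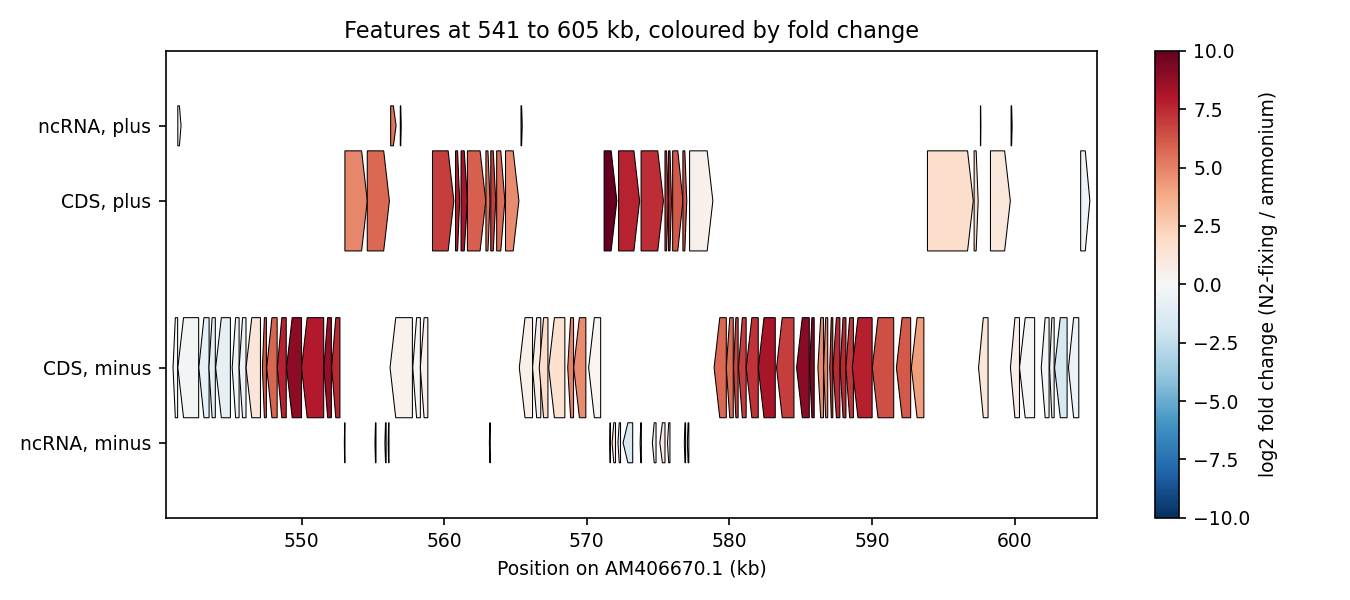
Map of the features in and around the stretch at 546104 to 599704, with position in kb on the horizontal axis and 1 row for each strand of CDS and ncRNA features, coloured by log2 fold change (N2-fixing over ammonium). Blocks of dark red CDS on both strands mark the stretch where 53 of 59 CDS rose, with paler features at both ends of the map.

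The 2 individual CDS with the strongest rises both lay in this stretch. The CDS azo0538, at 571215 to 572108 on the plus strand, rose from 4.84 ± 1.96 CPM (SD, n = 3) to 7796 ± 594 CPM (SD, n = 2), a log2 fold change of 10.64 with a standard error of 0.34 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.4e-07). The CDS azo0554, at 585625 to 585948 on the minus strand, rose from 0.779 ± 0.096 CPM to 484 ± 157 CPM, a log2 fold change of 9.25 with a standard error of 0.29 (edgeR adjusted p = 3.11e-07). Falls were smaller. The CDS azo2687, at 2962857 to 2963009 on the plus strand, dropped from 508 ± 231 CPM to 48.6 ± 7.54 CPM, a log2 fold change of -3.38 with a standard error of 0.45 (edgeR adjusted p = 0.00308). The CDS azo1280, at 1379865 to 1380641 on the minus strand, dropped from 366 ± 81.4 CPM to 40.1 ± 11.6 CPM, a log2 fold change of -3.19 with a standard error of 0.26 (edgeR adjusted p = 8.74e-05). The table pairs its CDS identifiers with no gene names, so the deleted gene, the nitrogenase genes and functional gene groups are not reported here.

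Across the genome, 1806 of 4836 tested CDS and ncRNA features were called at an adjusted p under 0.05, 945 higher and 861 lower under N2 fixation. Among them, 495 rose and 247 fell by 2-fold or more. Of 3909 CDS, 826 rose and 755 fell, with 430 and 190 of them changing at least 2-fold. Leaving out N2-fixing replicate 2 left 551 lower features, and leaving out N2-fixing replicate 1 gave 399 features that fell at least 2-fold. Among CDS the lower calls numbered 485 without N2-fixing replicate 2 and 503 with a replicate block, and 306 fell at least 2-fold without N2-fixing replicate 1. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

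**Figure D2:**
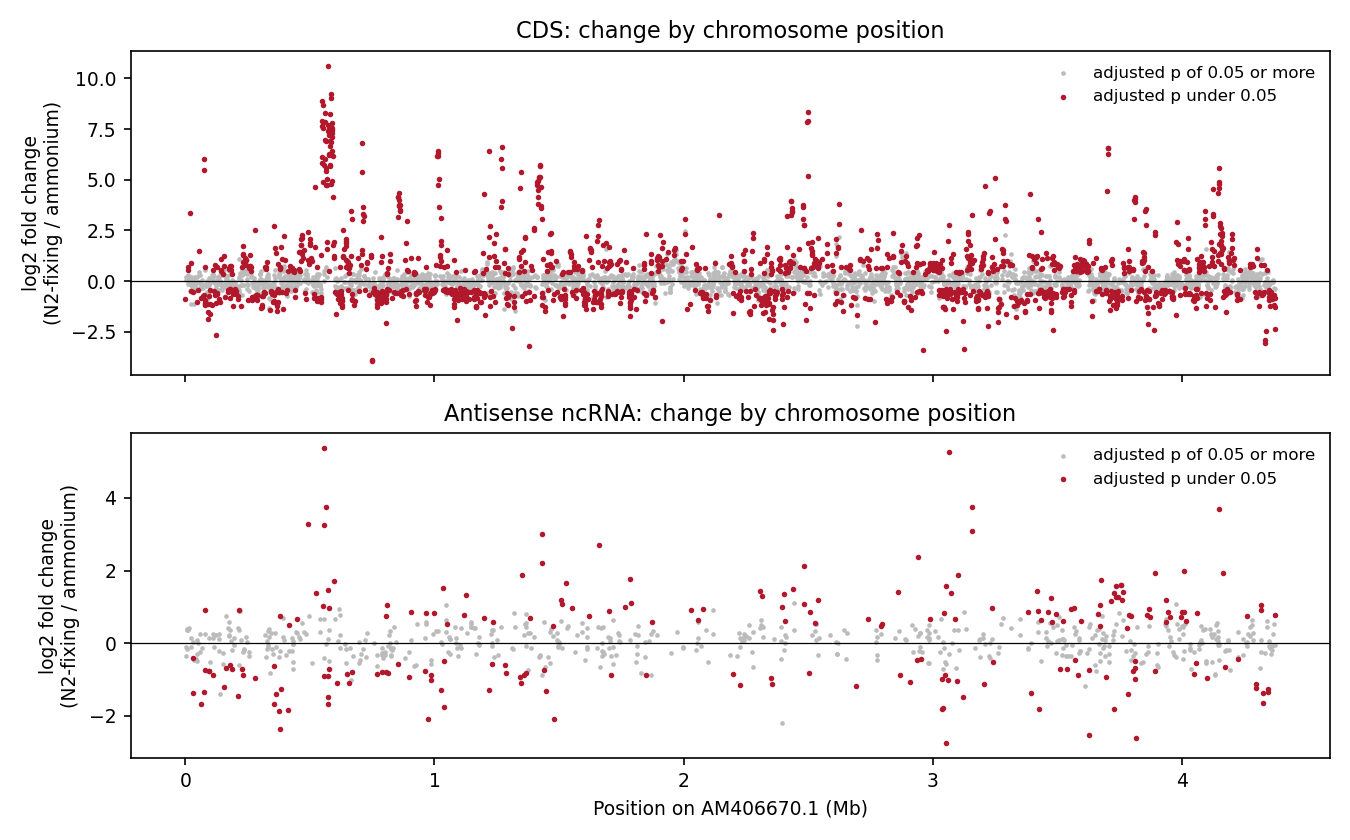
Log2 fold change (N2-fixing over ammonium) of each CDS (upper panel) and each antisense ncRNA (lower panel) against its position in Mb, with red points for adjusted p under 0.05 and grey points for the rest; the vertical scales differ. The CDS values near 0.57 Mb reach 10.64, while the antisense values reach 5.37.

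Changed CDS stood side by side. The genome held 19 runs of at least 7 adjacent tested CDS that all changed in the same direction. The longest run of higher CDS had 31 members and the longest run of lower CDS had 12, against at most 11 and 10 in 10000 shuffles of the calls along the genome, and no shuffle gave more than 3 runs. The shuffles moved each call on its own, while adjacent CDS can share reads or an operon. They show only that calls cluster, not why. Strong rises outside the main stretch included 15 CDS at 1413077 to 1430835 with a median log2 fold change of 4.75, which went from 0.0655% ± 0.00267 to 1.57% ± 0.102 of all counts. A run of 9 CDS at 1011215 to 1023464 had a median of 5.06, a run of 10 at 854050 to 864423 had 3.74, and a run of 7 at 3804339 to 3815732 had 3.89. At 4146076 to 4165737, 22 adjacent CDS rose with a median of 2.09. A longer but shallower run of 28 CDS at 3588679 to 3622981 had a median of 0.78. The 4 lower runs had medians from -1.04 to -0.74. The 12 CDS at 1782623 to 1792244 had a median of -0.91 and went from 1.32% ± 0.12 to 0.638% ± 0.141 of the counts, and the 9 CDS at 3738032 to 3742468 had a median of -0.81 and went from 1.78% ± 0.0335 to 0.947% ± 0.205. The run of 11 higher CDS at 2423317 to 2435838 had a median of 3.24, which was 1.21 without N2-fixing replicate 1 and 3.97 without N2-fixing replicate 2. It was 0.96 under the filter of 10 CPM, which kept 7 of the 11. The run length was chosen after seeing the data.

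Antisense transcription, the subject of the series title, was assessed on the 798 ncRNA features that overlap a CDS on the opposite strand. In the fit of antisense rows alone, 118 of them rose under N2 fixation and 106 fell, 54 and 46 by 2-fold or more. In the joint fit with CDS and other ncRNAs 104 rose and 91 fell, and under DESeq2 86 rose and 72 fell. Adjusted p-values from the antisense fit are not on the same footing as those given for CDS. As a class they took 1.61% ± 0.127 of the counts with ammonium (SD, n = 3) and 1.72% ± 0.0954 under N2 fixation (SD, n = 2), a difference of about the spread between libraries (exact two-sided permutation test, p = 0.4, where 3 against 2 libraries can give no p below 0.2). The antisense ncRNA at 556246 to 556625 on the plus strand, inside the main stretch, rose from 1.51 ± 0.203 CPM to 63.2 ± 1.29 CPM, a log2 fold change of 5.37 with a standard error of 0.22 (edgeR adjusted p = 4.52e-12, and 7.62e-07 in the joint fit). The CDS it lies opposite, at 556202 to 557770, had a log2 fold change of 0.35 and was not called (edgeR adjusted p = 0.134). Another in the same stretch, at 565387 to 565473 on the plus strand, rose from 1.28 ± 0.193 CPM to 17.3 ± 3.62 CPM, a log2 fold change of 3.74 with a standard error of 0.28 (edgeR adjusted p = 3.05e-08, and 2.63e-05 in the joint fit). Others in the stretch fell. The one at 572544 to 573220 on the minus strand went from 122 ± 7.95 CPM to 38.1 ± 4.13 CPM, a log2 fold change of -1.68 (edgeR adjusted p = 0.000119 in the joint fit). The CDS opposite it had a log2 fold change of 7.72. An abundant antisense ncRNA, at 3100875 to 3101334, rose from 552 ± 121 CPM to 2047 ± 771 CPM, a log2 fold change of 1.89 with a standard error of 0.24 (edgeR adjusted p = 0.000229, and 0.00162 in the joint fit). Among the falls, the antisense ncRNA at 3053251 to 3053307 on the plus strand dropped from 22.7 ± 9.2 CPM to 3.38 ± 0.377 CPM, a log2 fold change of -2.75 with a standard error of 0.39 (edgeR adjusted p = 0.000742). Without N2-fixing replicate 2 the calls came to 66 higher and 62 lower antisense ncRNAs, and without N2-fixing replicate 1 the changes of 2-fold or more came to 74 higher and 75 lower.

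Where an antisense ncRNA and the CDS opposite it were both called, they moved apart more often than together, in opposite directions in 83 of 124 pairs and in the same direction in 41. Across all 797 pairs the relation was weak, with a Spearman rho of -0.134 (95% interval -0.204 to -0.0645, permutation p = 0.0001, the smallest 10000 permutations can give, and 0.000333 adjusted over 10 relations). It was -0.0148 for the 184 with a same-strand CDS within 500 nt upstream. Over all 797 pairs, independent calls would give 50.2 opposite and 51 same pairs. These expected counts assume independence of being called as well as of direction. Within the 124 called pairs alone, the directions were not independent (Fisher's exact test, two-sided, p = 5.45e-05). The opposite pairs comprised 39 antisense ncRNAs that rose over a CDS that fell and 44 that fell over a CDS that rose. With 1 antisense ncRNA per CDS the counts were 67 opposite and 33 same pairs (Fisher's exact test, p = 0.000524). These tests treat pairs as independent, but neighbouring CDS changed together, so their p-values are likely too small. Opposite the CDS with a log2 fold change of 3 or more lay 40 antisense ncRNAs, of which 5 rose and 13 fell, with values from -2.60 to 3.01. The largest fall among these was at 3815167 to 3815223 on the minus strand, where the antisense ncRNA had a log2 fold change of -2.60 with a standard error of 0.33, and the CDS opposite it, at 3814395 to 3815732, one of 3.89. Tested directly, the antisense level relative to its CDS changed in 337 of 797 pairs, 158 higher and 179 lower under N2 fixation. Of the 179 that became lower relative to the CDS, 133 lay opposite a CDS that rose, and 94 were not called as antisense ncRNAs on their own. Without N2-fixing replicate 2 the opposite pairs numbered 36 and the same pairs 18, and 217 pairs changed in relative level. The pairing of directions was examined after seeing the data.

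**Figure D3:**
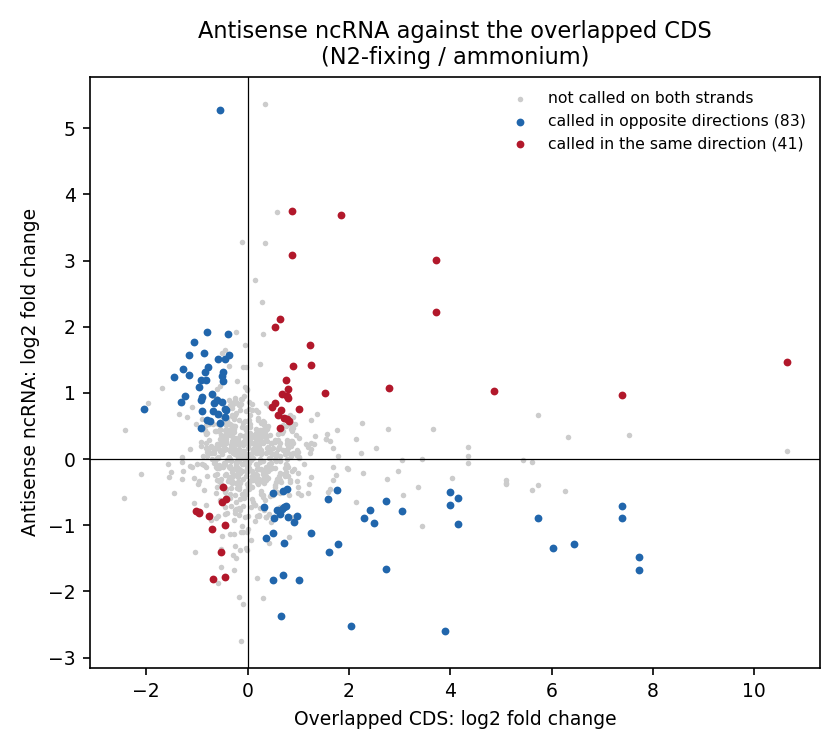
Log2 fold change (N2-fixing over ammonium) of each antisense ncRNA on the vertical axis against that of the CDS opposite it on the horizontal axis. Blue points are the 83 pairs called in opposite directions, red points the 41 called in the same direction and grey points the rest; at CDS values of 3 or more the antisense values run from -2.60 to 3.01.

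Of the 128 ncRNA features outside CDS, 15 were higher and 15 lower, though the counts were 15 and 26 without N2-fixing replicate 1 and 9 and 12 without ammonium replicate 1. Their share of the counts was 0.461% ± 0.0258 with ammonium and 0.384% ± 0.0191 under N2 fixation (exact two-sided permutation test, p = 0.2, the smallest possible). The strongest rises were at 3161900 to 3161975 on the minus strand, with a log2 fold change of 4.26, and at 2870994 to 2871163 on the plus strand, with 3.20. The strongest falls were at 2013769 to 2013827, with -1.58, and at 1067481 to 1067557, with -1.55. An abundant member, at 2820738 to 2820929, stood at 638 ± 26.5 CPM with ammonium and 645 ± 50.1 CPM under N2 fixation and was not called (edgeR adjusted p = 0.927).

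Most tRNA genes that changed were lower under N2 fixation. Of 50 tested, 22 fell and 2 rose, and adjusted over the list alone 23 fell and 3 rose. The feature at 3559218 to 3559501, labelled tRNA without an amino acid, is among the 50 and was not called. Their share of the counts was 4.09% ± 0.648 with ammonium (SD, n = 3) and 2.41% ± 0.14 under N2 fixation (SD, n = 2), with no overlap between the conditions (exact two-sided permutation test, p = 0.2, the smallest possible). The strongest falls came from 2 clusters. At 2308120 to 2308300 a tRNA-Arg gene had a log2 fold change of -2.21 (standard error 0.19, edgeR adjusted p = 0.000116) and its neighbouring tRNA-Pro gene went from 4480 ± 739 CPM to 1116 ± 334 CPM. The tRNA-His gene next to them, at 2307999 to 2308074, had a value of -0.11 and was not called. At 2269150 to 2269493 all 3 tRNA-Val genes fell, with values of -1.94, -1.63 and -1.67, while the tRNA-Val gene at 1162391 to 1162467 had -0.14 and was not called. The rises were the tRNA-Asn gene at 1771974 to 1772049, with a log2 fold change of 1.21 (standard error 0.16, edgeR adjusted p = 0.00102), and the tRNA-Arg gene at 1466272 to 1466348, with 0.58 (edgeR adjusted p = 0.0168). Another 6 tRNA genes, 3 pairs of tRNA-Ile and tRNA-Ala, held 0 counts in all libraries. How reads that match several gene copies were counted is not given in the sources used here, so these 0 values do not show that the genes were silent.

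**Figure D4:**
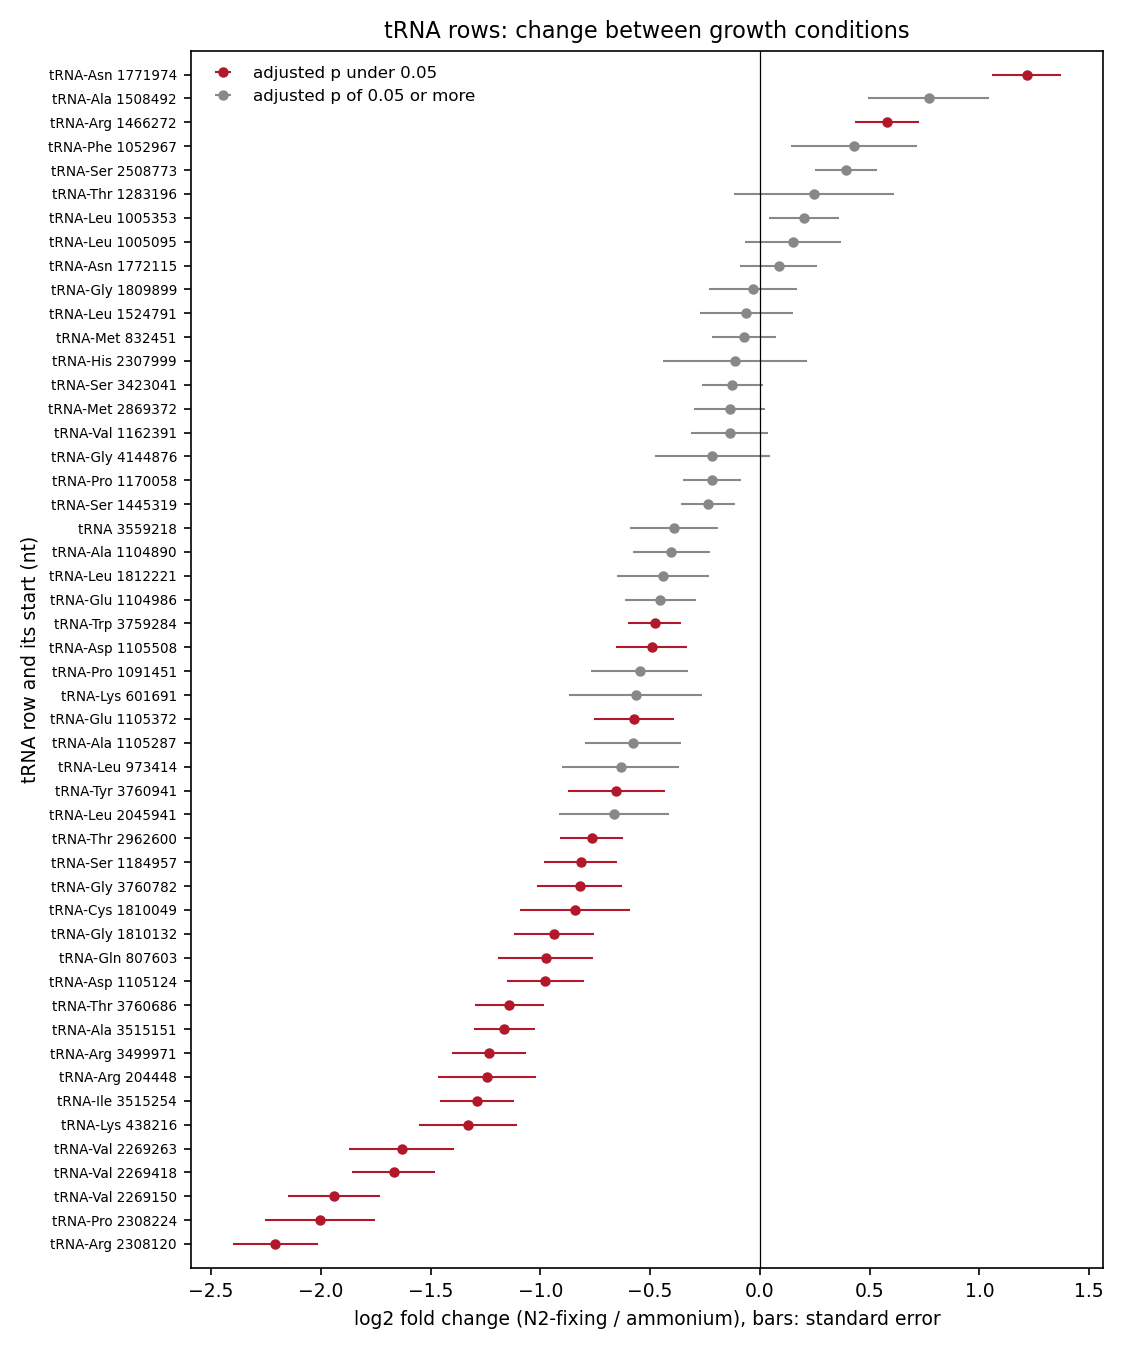
Log2 fold change (N2-fixing over ammonium) of the 50 tested tRNA genes, named by amino acid and start position, with bars for 1 standard error. The feature starting at 3559218 is labelled tRNA without an amino acid. Red points have an adjusted p under 0.05. Values run from -2.21 for a tRNA-Arg gene to 1.21 for a tRNA-Asn gene.

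As a class the tRNA genes had a median log2 fold change of -0.52 and were lower than the other features (limma camera with a preset correlation of 0.01, adjusted p = 5.85e-05). The call was lost with the estimated correlation of 0.363 (camera adjusted p = 0.885). The antisense and intergenic ncRNA classes were not called (camera adjusted p = 0.71 and 0.701). Only 18 tRNA genes lie at least a read length from any feature on their strand, and tested without the others 4 of these fell and 1 rose, with a class median of -0.16 that was not called (camera adjusted p = 0.321). With single ammonium libraries left out, 17 to 26 tRNA genes fell and 1 to 4 rose. The class median was -0.62 without N2-fixing replicate 1 and -0.47 without N2-fixing replicate 2. The tRNA class was chosen after seeing that the table names tRNA genes and no others.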

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

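Alternatives chosen after seeing the data were the stricter definition of antisense, leaving out features with a close neighbour, and rounding down, as were the tRNA class, the directions of antisense pairs and the relation to upstream CDS as results. Under DESeq2, limma-voom, median-ratio size factors, total counts, no filter, the 10 most abundant features left out, tRNA rows kept, the stricter definition of antisense and rounding down, each count of calls stayed within 1.5 times its main value. The CDS azo0538, azo0554, azo2687 and azo1280 kept their direction and their call wherever they were tested. Total counts moved the median log2 fold change of all features from 0.02 to -0.06 and the share of calls that were higher from 52.3% to 45.3%. The gene lists, and their alternatives, were not run.

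Requiring 10 CPM left fewer antisense ncRNAs to test, with 77 higher and 203 changed relative to the CDS. Without features that have a close neighbour, 1881 features remained: 641 were called, 338 higher and 303 lower, with 177 and 107 of them at least 2-fold, 118 antisense ncRNAs changed relative to the CDS, pairs called in opposite directions numbered 28 and in the same direction 14, and 4 tRNA genes fell and 1 rose. Fewer features were tested there, and the tRNA class median of -0.16 was not called (camera adjusted p = 0.321). With an estimated correlation the tRNA median of -0.52 was not called either (adjusted p = 0.885), and the cause was not tested.

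Leaving out each library in turn gave 551 to 938 lower features, 191 to 399 lower by 2-fold or more, 128 to 227 changed antisense ncRNAs (66 to 127 higher, 62 to 115 lower), 217 to 329 changed relative to the CDS, 36 to 85 opposite and 18 to 45 same pairs, and 1 to 4 tRNA genes higher. The lowest counts came without N2-fixing replicate 2, and for tRNA genes also without ammonium replicates 1 and 3; the 4 higher tRNA genes came without ammonium replicate 2. Where a single N2-fixing library was left, it was assumed to vary like the ammonium libraries.

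The replicate numbers are not said to mark a shared batch, and only 2 are shared. For this reason the numbers were not taken as pairs. Deviations from the group means correlated at 0.0656 for number 1 and -0.126 for number 2. The deviations of the 2 N2-fixing libraries are mirror images of each other, so these values cannot decide on pairing. With the number as a replicate block, 1277 features were called, 571 of them lower, 212 antisense ncRNAs changed relative to the CDS, and pairs numbered 54 opposite and 21 same.

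Libraries of 6862752 to 7678049 counts and 2 replicates in a group limit what can be called: in simulated data of this size 34% of 1.5-fold changes were recovered among CDS and ncRNA features, and 9.09% of 11 among antisense ncRNAs. The simulation changed a far smaller share of features than was called here, and only features above a minimum mean count. These rates may therefore not hold for the real libraries, least of all for sparse features.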

Other observations

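The relations to neighbouring genes, the directions of antisense pairs, the split of tRNA genes by neighbour and the test of a uniform loss of short RNAs were chosen only after the data were seen. Many antisense ncRNAs followed the gene that ends just upstream of them on the same strand. Of the 54 antisense ncRNAs that rose at least 2-fold, 19 lie within 500 nt downstream of a same-strand CDS, and in all 19 cases that CDS rose too. Examples are the ncRNA at 556246 to 556625, which starts 88 nt past a CDS with a log2 fold change of 5.73 and itself had 5.37 and the one at 565387 to 565473, 147 nt past a CDS with 4.75 and itself at 3.74. Falls had such neighbours as well: the ncRNA at 3053251 to 3053307, with -2.75, lies 240 nt past a CDS with -2.45. Others moved without one. The ncRNA at 3815167 to 3815223 fell by 2.60 on the log2 scale although the nearest upstream CDS, 640 nt away, had a value of -0.15 and was not called (edgeR adjusted p = 0.408).

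Transcription running on from the upstream CDS is a candidate explanation for part of the antisense changes. Across 184 antisense ncRNAs within 500 nt of an upstream same-strand CDS, the fold changes of both correlated with a Spearman rho of 0.678 (95% interval 0.573 to 0.768, Pearson r 0.821, permutation p = 0.0001, the smallest 10000 permutations can give, and 0.000333 adjusted over 10 relations). Of these, 131 lie 75 nt, the read length, or more away. Against the downstream same-strand CDS within 500 nt, 87 antisense ncRNAs gave a weaker correlation of 0.227 (95% interval 0.0136 to 0.427, permutation p of 0.05 adjusted over the same relations). This set was not cleared of ncRNAs with an upstream CDS equally close, such as the one at 491808 to 491895, with gaps of 157 nt upstream and 473 nt downstream. Running on could also reach the downstream CDS, so the comparison is not a clean control. Part of the upstream correlation could come from neighbours that change together. Reads of the overlapped CDS placed on the wrong strand are argued against as a general source. The 40 antisense ncRNAs opposite CDS with a log2 fold change of 3 or more had a median of -0.365, where frequent reads of this kind would raise it to 1 or more. The rate of wrong-strand reads was not estimated. A low rate would not move this median, so it cannot be excluded for the 5 of the 40 that rose, while 13 fell. What drives the opposite pairs stays open: among antisense ncRNAs more than 500 nt from an upstream CDS, 59 pairs were opposite and 30 the same (Fisher's exact test, p = 0.001), and a regulatory effect of growth on N2 was not tested apart from that. The tests of upstream and downstream CDS and of these pairs treat features as independent. Neighbouring CDS changed together, so their p-values are likely too small.

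The tRNA genes with a same-strand neighbour closer than a read length had a median log2 fold change of -0.58 (SD 0.738, 32 genes, 18 lower and 1 higher), against -0.19 (SD 0.597, 18 genes, 4 lower and 1 higher) for those that stand alone; this difference was not tested. A uniform loss of short RNAs in the N2-fixing libraries, as the only source of the tRNA changes, is argued against by the 2 tRNA genes called higher. The SD of the tRNA log2 fold changes of 0.711, which was 3.72 times their median standard error, argues against it as well. A partial loss on top of changes of single genes would give the same picture and is not excluded. For ncRNAs of up to 100 nt, the median log2 fold change differed by -0.0674 from that of longer ones (95% interval -0.152 to 0.0332). For these annotated ncRNAs, this argues against a loss of all short transcripts as large as the tRNA median of -0.52. A smaller loss stays open, and annotated lengths need not be the lengths of the RNAs. A lower tRNA level under N2 fixation, as a biological difference between the growth conditions, may also contribute and was not tested separately.

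Gene dosage along the replicating chromosome was examined because growth rate could differ between the conditions. The log2 fold change of 3909 CDS had a Spearman rho of 0.0413 with circular distance from the first base (95% interval 0.0128 to 0.0718, permutation p = 0.009, 0.018 adjusted over the 10 relations). The medians of 10 distance bins were uneven, from -0.10 in the nearest to 0.22 in the ninth and -0.03 in the farthest, midway round the chromosome. The interval and p-value treat CDS as independent. Neighbouring CDS changed together, so the interval is likely too narrow and the p-value too small. Dosage and other sources of this pattern cannot be told apart, because the place of the replication origin was not taken from an annotation. The interval, though likely too narrow, already lies on both sides of 0.05, the bound set for no drift. The rho itself was below 0.1, the bound set for dosage.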
